A study of Homo sapiens with 6 samples.

How the data were processed

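Cells of the HTR-8/SVneo line were grown with 5% fetal bovine serum, and for exosomes with 5% serum depleted of exosomes by ultracentrifugation, for 48 h, per the labels' protocols. Exosomes were pelleted from cleared and filtered medium at 120000 g for 75 min, and washed and pelleted again. Small RNA libraries were made with a QIAseq miRNA kit from 1 to 500 ng of RNA, per the labels' protocols. Use of that kit's molecular tags was not given in the sources used here. The reads were aligned with Bowtie to GRCh38, per the submitters' processing notes. The miRNA reference, the counting tool and any filter were not given in the sources used here.

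The deposited table gave RPM values that the authors computed for 1169 entries in 6 libraries, of which 1056 were named human miRNAs and 113 were entries without a miRNA name. Each library's RPM values summed to 1000000 over all entries. All values, 100% in each library, were whole multiples of the smallest value within a tolerance of 0.01, so reads were recovered by division. In the exosome libraries only 33, 22 and 25 entries lay within 20 steps of 0, so the step rests on fewer values there. Totals, summed over entries, ran from 10880303 to 12294416 reads in cells and from 1542485 to 2641870 in exosomes. A count of 3 reads, the limit that a value of 0 allows, was 0.244 to 0.276 RPM in cells and 1.14 to 1.94 RPM in exosomes. Reads amplified by PCR are not independent molecules, so these limits cover counting error only.

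The design set before the data were examined assumed edgeR for counts and limma-trend for other units. Since the deposited unit was RPM, limma-trend on log2(RPM + 1) was the main test, with named miRNAs at 1 RPM or more in at least 3 libraries and Benjamini-Hochberg adjustment at 0.05. Fold changes on this scale understate the change of low miRNAs. RPM values are shares of a fixed total, so a large change in abundant miRNAs shifts all others. TMM scaling of the recovered reads would shift every log2 change by -0.34, and the median log2 change of all tested miRNAs was -1.56, or -0.45 for the 225 with at least 100 RPM in either group. The 22 miRNA lists were fixed before the data were examined. Lists with at least 3 tested members were tested with camera at a preset correlation of 0.01 and with an estimated correlation, and with fry. Shares of reads and numbers of detected miRNAs were compared with exact two-sided permutation tests.

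Named miRNAs followed a rule set in advance. It took miR-1290, miR-1246 and miR-210-3p, then the 8 miRNAs with the largest change in each direction that passed the test, had a mean of at least 100 RPM in the higher group and did not overlap between groups. It also took the 5 most abundant miRNAs of each group and up to 4 tested members of each list with the smallest adjusted p. miRNAs named as exceptions within a list count, namely let-7d-3p, miR-92a-3p and miR-10401-3p, were chosen after their values were seen.

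The samples' replicate numbers were not treated as pairs. Replicates differed by more than the counting noise of reads (chi-square per degree of freedom from 111 to 330). Amplification can add to such differences, so this does not show that they were separate cultures, and each library was counted as 1 sample. Near-identical miRNAs shared reads. The 8 groups with identical reads in all libraries included miR-100-5p with miR-99a-5p and miR-199a-3p with miR-199b-3p, and miR-103a-3p and miR-107 differed by at most 0.039%. Values of single members of near-identical families, such as let-7, miR-29 and miR-320, are therefore uncertain. Family shares and library totals can count reads more than once. Hairpin positions came from GENCODE release 29 on GRCh38, which gave a hairpin for 537 of the 545 tested miRNAs.

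The main test was tested on simulated data for the exosome and cell comparison, with 20 simulations that changed 200 miRNAs under 200 RPM in cells. With reads drawn independently, a mean of 648.3 miRNAs were tested, 93.8% of 4-fold decreases and 98.0% of 4-fold increases were recovered, as were 99.8% and 100% of 16-fold ones, and 5.5% of calls were unchanged miRNAs. With exosome reads drawn as molecules of 100 reads each, a setting chosen after seeing the data, a mean of 590.1 miRNAs were tested. Recovery was then 74.4% and 27.4% for 4-fold decreases and increases and 95.0% and 58.5% for 16-fold ones, and 56.3% of calls were unchanged miRNAs, nearly all of them low in cells.

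Alternatives were the pseudocount, the filter, a replicate block, edgeR, DESeq2 and limma-voom on the recovered reads, a minimum fold of 2 and leaving out each library. A pseudocount of 50, group weights, thinned reads, unnamed entries, identical entries counted once, edgeR with TMM scaling and thinned minimums of 1 and 10 reads were added after seeing the data. Recovered reads in edgeR with TMM scaling gave 311 calls among 511 miRNAs, 86 higher and 225 lower. Versions were R 4.3.3, limma 3.58.1, edgeR 4.0.16, DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.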

Results

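Small RNA was sequenced from HTR-8/SVneo, an immortalised human first-trimester extravillous trophoblast line, and from exosomes pelleted from the medium of these cells. The 6 libraries comprised 3 of cells and 3 of exosomes, and the abundance of 1056 named human miRNAs was given as RPM, the reads of a miRNA scaled to a library total of 1000000. Whole reads were recovered from the RPM values. Summed over entries, which can count shared reads more than once, the cell libraries held 12294416, 10880303 and 11112501 reads. The exosome libraries held 1542485, 1888079 and 2641870. The labels did not say that the 3 samples of a group were separate cultures, so p-values measure the spread between these samples, which may be technical. All levels below are mean ± SD over 3 libraries per group unless stated otherwise.

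The main comparison asked which miRNAs were higher or lower in exosomes than in the cells. Exosomes carried far more of miRNAs typical of liver and blood, namely miR-122-5p, miR-486-5p, miR-150-5p, miR-223-3p and miR-451a, and of miRNAs from the imprinted chromosome 14 cluster such as miR-432-5p and miR-409-3p. The medium contained serum, and RNA carried over from it could not be told apart from export by the cells. Cells carried more miR-21-5p, a growth-associated miRNA, which stood at 180082 ± 22112 RPM in cells and 15377 ± 5552 RPM in exosomes, an 11.7-fold difference. They also carried more of the miR-29 and miR-30 families, miR-17-5p and miR-27a-3p. Of 545 miRNAs tested with limma-trend and Benjamini-Hochberg adjustment, 361 passed an adjusted p of 0.05, with 102 higher and 259 lower in exosomes. Among the abundant miRNAs, 80 of 176 with a mean of at least 100 RPM in exosomes were higher there. Of 171 with at least 100 RPM in cells, 91 were lower in exosomes, 31 were higher and 49 did not pass. Of the 259 lower ones 155 had 0 reads in every exosome library. The lower count rests on rare miRNAs, since 168 of the 259 lay under 100 RPM in cells and data simulated with 100 reads per molecule, a setting chosen after seeing the data, gave a mean of 157.2 unchanged miRNAs called lower among 590.1 tested, of which 4.1 lay at 100 RPM or more. Leaving out a cell library gave 149 to 164 calls among 365 to 367 tested, with 82 to 88 higher and 67 to 76 lower. The filter at 1 RPM in at least 3 libraries then removed every miRNA with 0 reads in all exosome libraries. That forced part of this drop. With limma-voom on the recovered reads 163 passed, with 67 higher and 96 lower.

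miR-122-5p, the dominant hepatocyte miRNA, had the largest log2 change on the RPM + 1 scale among the abundant miRNAs, going from 9.73 ± 3.81 RPM in cells to 38772 ± 1779 RPM in exosomes. That change was 11.88 ± 0.29 (SE, limma-trend adjusted p = 1.47e-05). Its hairpin lies on chromosome 18 at 58451074 to 58451158 (GRCh38, plus strand), within an exon of the non-coding gene MIR122HG. The next by this scale was miR-432-5p, at 0.583 ± 0.699 RPM in cells, from 17, 3 and 1 reads, and 5117 ± 831 RPM in exosomes, with its hairpin on chromosome 14 at 100884483 to 100884576 (plus strand) in an intron of the non-coding gene AL117190.1. The order of miR-122-5p and miR-432-5p turned with a pseudocount of 0.1, which gave log2 changes of 12.02 and 13.39. miR-486-5p, abundant in red blood cells, rose from 3.30 ± 2.62 to 7002 ± 779 RPM. The leukocyte miRNAs miR-150-5p and miR-223-3p reached 2447 ± 751 and 1704 ± 97.2 RPM in exosomes against 2.41 ± 3.57 and 1.23 ± 1.97 RPM in cells. Their cell levels came mostly from cell replicate 1, with 80, 0 and 8 reads of miR-150-5p and 43, 1 and 1 of miR-223-3p. miR-409-3p rose from 1.13 ± 0.27 to 1330 ± 166 RPM, and the erythroid miR-451a from 0.298 ± 0.517 to 670.1 ± 192.3 RPM. miR-6529-5p had 0 reads in every cell library and 860.3 ± 310 RPM in exosomes.

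On the same log2 scale the largest decreases among miRNAs with at least 100 RPM in cells were those of miR-31-3p, miR-4521, miR-1307-5p, miR-455-5p, miR-32-5p, miR-582-3p, miR-330-5p and let-7i-3p. miR-31-3p stood at 330.2 ± 75.0 RPM in cells and had 0 reads in all 3 exosome libraries. miR-4521 and miR-455-5p also had 0 reads in exosomes, against 241.2 ± 82.4 and 169.1 ± 20.5 RPM in cells. miR-582-3p fell from 1826 ± 135 to 51.2 ± 80.9 RPM, with exosome libraries at 144.6, 1.59 and 7.57 RPM. miR-32-5p fell from 428.6 ± 76.3 to 12.8 ± 22.1 RPM and was found in 1 exosome library alone. Its call was lost with edgeR on the recovered reads (adjusted p = 0.0742 with TMM scaling).

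**Figure D1:**
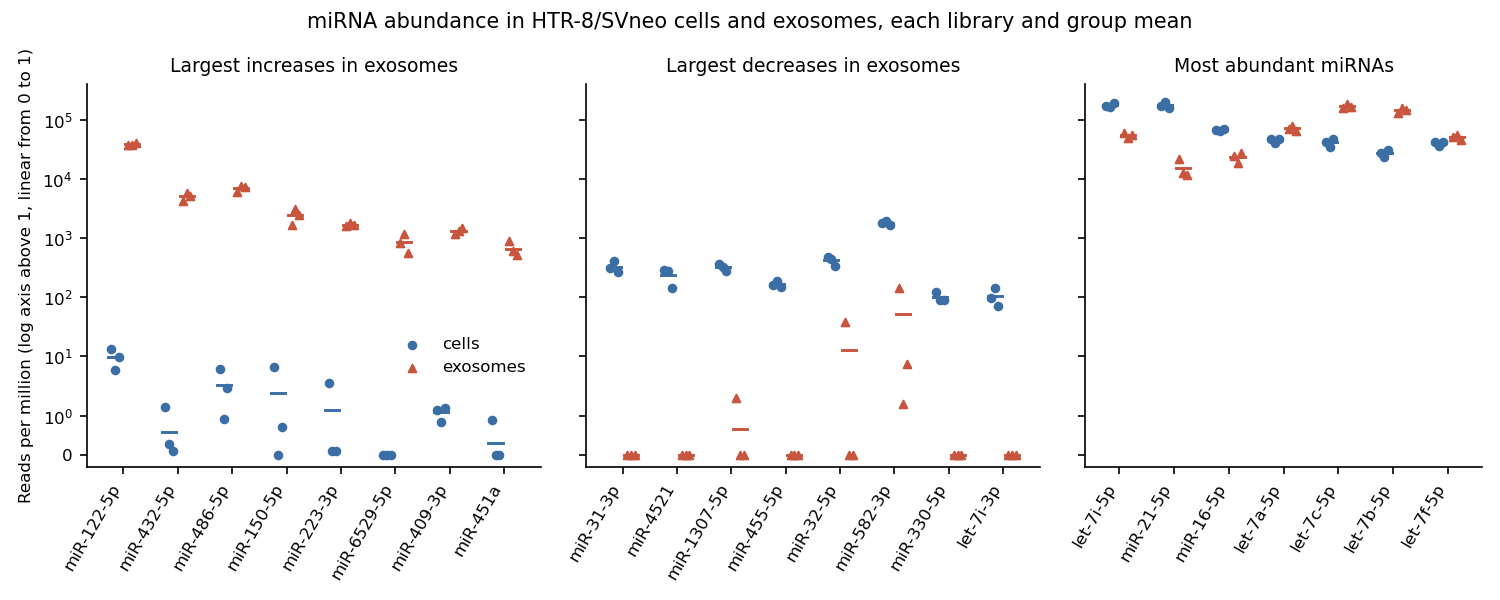
RPM of the 8 miRNAs with the largest increases and the 8 with the largest decreases in log2(RPM + 1), and the most abundant miRNAs, on an axis that is logarithmic above 1 and linear below; points are single libraries (circles for cells, triangles for exosomes) and bars are group means of 3 libraries. miR-122-5p goes from 9.73 RPM in cells to 38772 RPM in exosomes, while miR-21-5p goes from 180082 to 15377 RPM.

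The most abundant miRNAs of both groups came largely from the let-7 family, which regulates developmental timing and differentiation. In cells let-7i-5p (180753 ± 14860 RPM) and miR-21-5p led, followed by miR-16-5p, let-7a-5p and let-7c-5p. In exosomes let-7c-5p (173947 ± 14767 RPM) and let-7b-5p (146348 ± 12662 RPM) led, 4.16-fold and 5.34-fold above their levels in cells. let-7i-5p was 3.27-fold lower in exosomes, at 55237 ± 4863 RPM. Of 18 tested let-7 entries 6 were higher and 7 lower, so the family had no common direction. The higher ones were mature 5p strands and let-7d-3p, and 4 of the 7 lower ones were 3p strands with 0 reads in exosomes. The median log2 change was -1.19, while camera gave an upward direction that did not pass (adjusted p = 0.502) and fry, which tests movement in one direction on balance, gave a downward one (adjusted p = 0.000335). The share of all reads in the family was 36.8% ± 3.2 in cells and 53.9% ± 3.6 in exosomes (exact permutation p = 0.1, two-sided, the smallest that 3 against 3 allows). The increases of let-7a-5p (1.59-fold) and let-7f-5p (1.26-fold) did not pass with edgeR and TMM scaling, and that of let-7f-5p changed sign with limma-voom.

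miRNAs of the chromosome 14 cluster (C14MC), an imprinted cluster expressed in placenta, were higher in exosomes for 14 of 21 tested members, while 7 did not pass and 0 were lower. The table held 50 members, and only 10 of the 21 tested had a cell mean of at least 1 RPM. The others passed the filter chiefly through their exosome levels and could hardly be called lower. The counts and the list test therefore rest partly on the filter. miR-382-5p went from 5.03 ± 1.42 to 1802 ± 363.1 RPM and miR-379-5p from 8.53 ± 2.28 to 1454 ± 132.8 RPM. The cluster held 0.00538% ± 0.00099 of the reads in cells and 1.25% ± 0.09 in exosomes. The camera test passed with the preset correlation of 0.01 (adjusted p = 1.59e-09), and the call was lost at adjusted p = 0.0554 with an estimated correlation. Of the primate-specific placental cluster on chromosome 19 (C19MC), 15 members were in the table and 1 could be tested. That member, miR-516a-5p, had 12.7 ± 3.7 RPM in cells and 0 reads in exosomes. miRNAs found in a single exosome library had medians of 35.6 to 45.4 RPM, so 0 reads do not show its absence at that level. The neighbouring cluster of miR-371, miR-372 and miR-373 had 0 entries in the table.

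The lists of miRNAs from other cell types were measured because the medium contained serum. All 4 erythroid entries and all 5 leukocyte entries were higher in exosomes. miR-144-5p, an erythroid miRNA, rose from 0.830 ± 0.726 to 407.1 ± 75.7 RPM, and miR-142-3p, a pan-leukocyte miRNA, from 42.2 ± 8.6 to 13874 ± 5043 RPM. Both lists passed camera with the preset correlation (adjusted p = 0.000528 and 0.000102), and neither did with an estimated correlation (adjusted p = 0.207 and 0.0982). The erythroid share of reads was 0.000445% ± 0.000365 in cells and 0.819% ± 0.067 in exosomes, and the leukocyte share was 0.00496% ± 0.00136 and 1.97% ± 0.48. Of 3 tested liver entries only miR-122-5p rose, while miR-192-5p (421.8 ± 48.3 and 429.7 ± 149 RPM) and miR-194-5p (42.8 ± 18.6 and 69.98 ± 40.2 RPM) did not pass. Both strands of miR-126, an endothelial miRNA, were higher, with miR-126-3p at 1855 ± 95.8 RPM in cells and 14434 ± 1324 RPM in exosomes. Among 2 muscle entries miR-206 rose from 0 reads to 73.6 ± 36.6 RPM and miR-1-3p did not pass. Of 6 neural entries 3 were lower and 0 were higher, with miR-128-3p falling from 931.0 ± 128.5 to 423.4 ± 143 RPM. The liver and neural lists did not pass camera (adjusted p = 0.139 and 0.818).

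In each of 6 further family lists more entries were lower than higher in exosomes, as were 259 against 102 of all tested miRNAs. Of 18 entries of the miR-29 and miR-30 families, of which miR-29 represses extracellular matrix genes, 14 were lower, 10 of them with at least 100 RPM in cells, and 0 were higher. miR-29a-3p fell 17.5-fold, from 8670 ± 680 to 496.8 ± 123.6 RPM, and miR-30a-5p fell 4.42-fold, from 21913 ± 919 to 4954 ± 728 RPM. This was the only family list lower as a set in camera (adjusted p = 0.024), and the call was lost with an estimated correlation (adjusted p = 0.400). In the miR-17-92 family, which promotes proliferation, 11 of 19 entries were lower, 9 of them with at least 100 RPM in cells, and 2 were higher. miR-17-5p fell 6.09-fold to 457.7 ± 61.1 RPM, while miR-92a-3p rose 1.62-fold to 5709 ± 749 RPM. In the miR-15/16 family 9 of 14 were lower, 5 of them with at least 100 RPM in cells, and 1 was higher, with miR-16-5p falling 2.84-fold to 23898 ± 4858 RPM. In the miR-23/24/27 clusters 6 of 11 were lower, 5 of them with at least 100 RPM in cells, and 2 were higher, and miR-27a-3p fell 7.20-fold to 1332 ± 300 RPM. For miR-221 and miR-222, 2 of 4 were lower, 1 of them with at least 100 RPM in cells, with miR-221-3p falling 4.56-fold and miR-222-3p at 728.1 ± 75.8 and 718.4 ± 180 RPM. Of the epithelial miR-200 family 3 of 6 were lower and 1 higher, and only 1 lower entry, miR-141-3p, had at least 100 RPM in cells. miR-141-3p fell 35.8-fold to 5.68 ± 9.83 RPM, with reads in 1 exosome library alone, and miR-200c-3p rose 1.91-fold to 427.0 ± 42.1 RPM. Both of these calls were lost with edgeR and TMM scaling (adjusted p = 0.0501 and 0.11). The lists from miR-17-92 to miR-200 did not pass camera.

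All 5 tested entries of the miR-320 family were higher in exosomes. miR-320b rose from 534.6 ± 135 to 3739 ± 573 RPM and miR-320d from 31.1 ± 14.7 to 922.3 ± 90.0 RPM. The family passed camera with the preset correlation (adjusted p = 0.000303) but not with an estimated correlation (adjusted p = 0.400), and its members are near-identical, so reads could be counted to several of them. Among 4 mirtrons, which are spliced from short introns, miR-1236-5p (0 reads in cells, 67.3 ± 25.4 RPM in exosomes) and miR-877-5p (56.2 ± 19.2 and 306.6 ± 89.3 RPM) rose, with camera at adjusted p = 0.0463 and 0.291 with an estimated correlation. Of 12 entries that overlap other RNAs 3 were higher (miR-1290, miR-1246 and miR-10401-3p) and 4 lower, with a median log2 change of -1.14, a mean of -0.58 and an upward camera direction that did not pass (adjusted p = 0.502). Of miRNAs listed as vesicle-enriched in T cells, both tested ones, miR-451a and miR-125a-3p, were higher, although miR-451a is also in the erythroid list. Of 5 listed as retained in T cells 4 were lower and let-7a-5p was higher, and the list did not pass camera (adjusted p = 0.502). The hypoxia-induced miR-210-3p stood at 166.1 ± 22.0 RPM in cells and 66.97 ± 59.7 RPM in exosomes, with 0 reads in 1 exosome library, and did not pass (limma-trend adjusted p = 0.217). Adjusted over the list alone, the counts of calls were the same for every list except the miR-17-92 family, which then had 3 higher and 12 lower. All 16 lists with at least 3 tested members passed fry, which does not compare a list with other miRNAs.

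**Figure D2:**
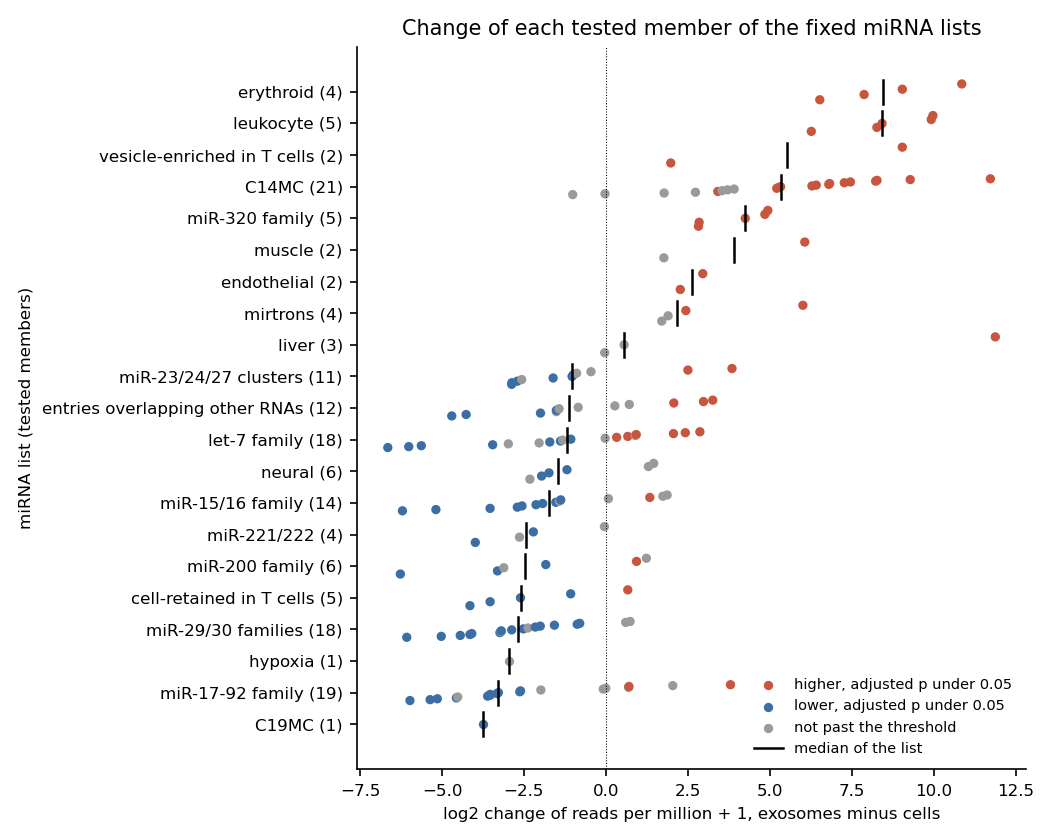
log2 change of RPM + 1, exosomes minus cells, for each tested member of the miRNA lists (1 point per miRNA; red higher, blue lower, grey not past an adjusted p of 0.05 in limma-trend), with the number tested in brackets and the median as a black line. The erythroid, leukocyte, C14MC and miR-320 members lie to the right, with medians of 8.46, 8.43, 5.33 and 4.25, and the miR-29/30 median is -2.70.

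The composition of the libraries was compared with shares of each library's total and with numbers of detected miRNAs. A minimum of 1 RPM is under 3 reads in exosomes, where 3 reads were 1.14 to 1.94 RPM. In cells 3 reads were 0.244 to 0.276 RPM. The 10 most abundant miRNAs held 64.9% ± 1.1 of the reads in cells and 65.8% ± 2.7 in exosomes, a difference within the spread between replicates (exact permutation p = 0.7, two-sided). The shares of 20 of 21 lists did not overlap between the groups, where chance gives 10% of lists for 3 against 3. Of all 545 tested miRNAs 393 also did not overlap, and lists that share members or a fixed total are not independent. Each of these 20 lists had an exact permutation p of 0.1, or 0.105 after Benjamini-Hochberg adjustment, so none could pass 0.05 in this design. Cells had 651.7 ± 16.5 named miRNAs at 1 RPM or more and exosomes 328.7 ± 20.1 (exact permutation p = 0.1). After thinning to 1542485 reads per library the numbers with at least 5 reads were 466.7 ± 17.67 and 321.3 ± 19.04. At a minimum of 10 RPM they were 322.7 ± 4.5 and 315.0 ± 18.5, which overlapped between the groups (exact permutation p = 0.6).

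miR-1290 is the miRNA named in the study's title, as an exosomal signal from trophoblast to endometrium. It was found in all 3 exosome libraries and in 0 of the 3 cell libraries. Its reads were 4, 7 and 9 in exosomes, or 3.24 ± 0.58 RPM, against 0 among 34287220 reads of the cell libraries, a total summed over entries. A count of 0 allows up to 0.244 to 0.276 RPM in the cell libraries, a limit that covers counting error only. The hairpin lies on chromosome 1 at 18897071 to 18897148 (GRCh38, minus strand) in an intron of ALDH4A1 and of the overlapping gene AL080251.1. The limma-trend log2 change on the RPM + 1 scale was 2.07 ± 0.16 (SE, adjusted p = 0.000129), and an exact permutation test of the RPM values gave p = 0.1, the smallest that 3 against 3 allows. miR-1246, which like miR-1290 is in the list of entries that overlap other RNAs, rose from 0.559 ± 0.589 to 10.98 ± 3.01 RPM (limma-trend adjusted p = 0.00104). The call for miR-1290 was lost when any cell library was left out (adjusted p = 0.245 to 0.287), at an unchanged log2 change of 2.07. The reads of miR-1290, and the 13, 27 and 27 reads of miR-1246, were also few beside those of miRNAs found in a single exosome library and in no cell library, whose medians were 70, 78 and 94 reads. Of 13, 12 and 9 such miRNAs, 0, 2 and 1 had under 10 reads.

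**Figure D3:**
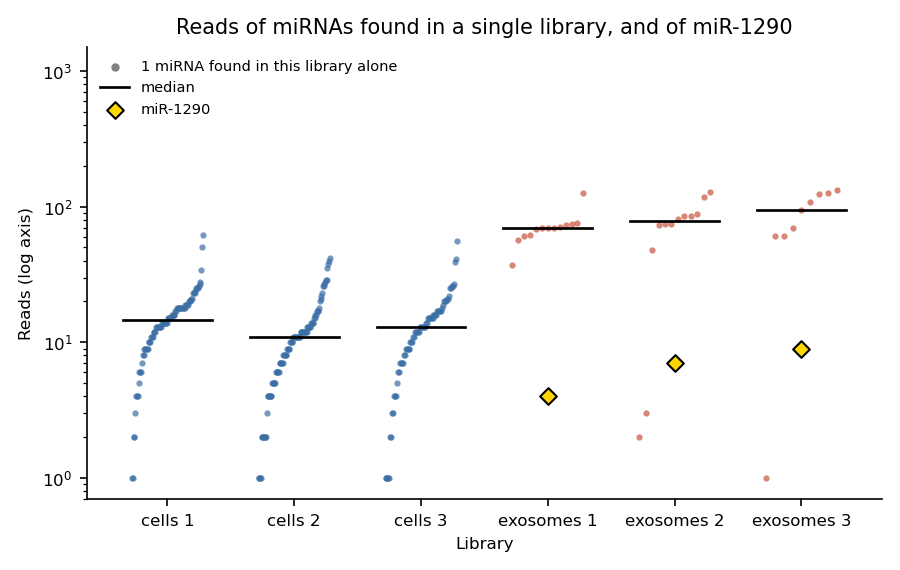
Reads, on a logarithmic axis, of each miRNA found in that library and in no other (dots), with the median as a black line, for the 3 cell and 3 exosome libraries; diamonds mark miR-1290, which was found in all 3 exosome libraries. The medians are 14.5, 11 and 13 reads in cells and 70, 78 and 94 reads in exosomes, and miR-1290 had 4, 7 and 9 reads.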

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

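All tests of explanations in this part were chosen after the results were seen. The entries without a miRNA name, which enter no comparison above, stood out because their signal in exosomes exceeded that in cells. They held 2.628% ± 0.488 of the reads in exosomes and 0.232% ± 0.006 in cells. The 3 largest made up 92.8% of that signal in exosomes, at 14238 ± 3251, 7058 ± 1566 and 3103 ± 896 RPM against 260.0 ± 43.8, 191.9 ± 30.8 and 15.96 ± 4.15 RPM in cells. Groups of 3 libraries are too small for a test of outlying samples.

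The real split of the 6 libraries gave 361 calls and the highest of the other splits gave 0. It was the 1 of 10 splits with as many calls, and 10 splits are too few for a share under 0.05.

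The first pattern is the rise of erythroid, leukocyte and C14MC miRNAs and miR-122-5p in exosomes. The 24 called members all had more reads, before any scaling, in every exosome library than in any of the deeper cell libraries. For these members lower read depth is argued against. They were picked by their rise, and the 7 C14MC and 2 liver members that did not pass were left out. RNA carried over from serum in the medium stays open: 10 of 12 erythroid, leukocyte and liver members were higher and 1 of 8 neural and muscle members was (two-sided Fisher exact p = 0.00452), but this restates the pattern, with comparison lists picked after their counts were seen, and both endothelial members were higher too. The most abundant of them were miR-122-5p at 38772 RPM and miR-142-3p at 13874 RPM, and the serum had been depleted of exosomes. In cells 8 of the 12 had at least 1 RPM and 3 had at least 10 RPM. The 3 included miR-192-5p and miR-194-5p, which did not pass. Of 21 tested C14MC members 10 had at least 1 RPM in cells and 0 had at least 10 RPM. miRNAs found in a single cell library had medians of 1.01 to 1.18 RPM, so levels near 1 RPM are uncertain. Selective export from the cells cannot be told apart from serum carry-over, because no library of unconditioned medium was analysed here. The cell libraries held 65 to 167 reads of miR-122-5p, against 59208 to 107555 in the exosome libraries. Whether these few reads came from miRNA made by the cells was not tested.

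The second pattern is that miRNAs with many reads were missing from single exosome libraries: of 392 with at least 50 reads in a thinned exosome library 163 (41.6%) had 0 reads in another. Lower read depth is argued against, because this held for 0 of 257 miRNAs in cell libraries thinned to the same depth. Few captured molecules, each amplified to many reads, may account for it, but the draws made for this cannot decide. miRNAs found in a single exosome library had medians of 70, 78 and 94 reads. If each were a molecule, the libraries would hold about 22036, 24206 and 28105 molecules. Cell libraries drawn down to those numbers gave 46.7% ± 1.6 (SD over 20 draws). Those numbers rest on miRNAs missing from the other exosome libraries, which is the pattern itself. Each drawn molecule also stood for many reads. The same draws gave a similar 48.0% on an earlier measure, the share missing from at least 1 library. They detected a mean of 276.3 miRNAs per library against 339.0 in exosomes. The 50-read measure replaced the earlier one after its value was seen, because unthinned cell libraries gave 42.0% on the earlier one against 49.7% in exosomes. Differences between exosome preparations were not tested.

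The third pattern is miR-1290 in exosomes but not in cells. The cell libraries held 0 reads of it that index misassignment could have passed on, but that is part of the pattern and not a separate test. Whether its reads come from captured miR-1290 molecules stays open: they were at most 0.148 of the lower quartile for miRNAs found in a single library, but that is the observation that raised the doubt, not a test of it. Rare molecules that amplified poorly, or release of miR-1290 by the cells at a low level, were not tested.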

How the results depend on the processing

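Alternatives named as added in the processing summary were chosen after seeing the data. Of 79 named miRNAs other than miR-1290, 52 had a value under all 22 alternatives, and 39 of these kept their direction and their side of the threshold throughout. A filter removed the other 27 under at least 1 alternative, mostly on leaving out a cell library, and 16 of them kept both wherever they had a value. Of the values of all 79, 1578 kept both, 61 lost their call, 4 gained one and 8 changed direction. The direction changes were in values near 0, namely miR-222-3p (0.018 with edgeR and total counts, -0.22 to 0.14 on leaving out a library), miR-192-5p (0.064 with edgeR and total counts, -0.22 to 0.29 on leaving out a library) and let-7f-5p (-0.0096 with limma-voom), and the cause was not tested. The total of 361 calls became 218 with a mean of at least 10 RPM, which tests fewer miRNAs, with 118 lower. It became 163 with limma-voom, with 67 higher and 96 lower, and the cause was not tested. Leaving out a library gave 149 to 390 calls and 67 to 290 lower ones, lowest without a cell library (149, 151 and 164, with 82, 82 and 88 higher). The filter then tested 365 to 367 miRNAs, with none of those at 0 reads in all exosome libraries. Calls were also lost among miRNAs still tested, and the cause of that part was not tested. The log2 change of miR-1290 stayed at 2.07 without a cell library but its adjusted p rose to between 0.245 and 0.287, and the cause was not tested. With all 6 libraries its adjusted p was 1.32e-05 to 0.00644. Over the 18 alternatives with a value the log2 change of miR-1290 ran from 0.090 to 7.49, so its size depended on the processing. miR-1290 had no value without an exosome library or at a mean of at least 10 RPM, since the filter then removed it. The 6 lists called by camera became 0 with an estimated correlation (3 at an unadjusted p under 0.05) and 3 to 6 on leaving out a library (3 without exosome replicate 3), and the cause was not tested. The mirtron list lost its call under more settings than any other list. The difference in detected miRNAs, -323 at 1 RPM, was -417 at 0.1 RPM and -7.67 at 10 RPM. It was -428, -412 and -358 at 1, 5 and 10 reads, and -364, -145 and -58.7 after thinning, so it depended on the minimum. The replicate numbers gave no sign of pairing, with correlations of deviations of 0.0054, -0.023 and 0.016 for same-numbered libraries. Not every library correlated best with its own number. Noise in the exosome libraries could hide a pairing, so this does not show that the samples were unpaired. With the replicate block 352 miRNAs were called, 97 higher and 255 lower. Recovered depth sets 1.14 to 1.94 RPM as the limit of a 0 in exosomes, but miRNAs found in a single exosome library had medians of 35.6 to 45.4 RPM, so levels near or under these are uncertain.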

Other observations

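Some abundant miRNAs outside the lists and the naming rule, chosen after their values were seen, also differed. miR-191-5p rose from 10992 ± 789 to 44987 ± 12065 RPM, miR-423-5p from 551.7 ± 346 to 15315 ± 5821 RPM and miR-193b-5p from 37.4 ± 12.1 to 2334 ± 197 RPM. miR-125a-5p rose 2.48-fold and miR-342-3p 4.45-fold. In the other direction miR-374a-5p fell 91.1-fold, from 3458 ± 556 to 37.96 ± 6.67 RPM. miR-34a-5p, a target of p53, fell 4.63-fold to 1297 ± 442 RPM, and miR-31-5p, the other strand of the strongly depleted miR-31-3p, fell 3.27-fold to 2718 ± 850 RPM. All 8 passed limma-trend at an adjusted p of 0.05.

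Where both strands of a hairpin were called, opposite directions were fewer than independent strands would give. Of 135 hairpins with both strands tested 61 had both called, and 7 of these rose on both strands, 42 fell on both and 12 moved in opposite directions, where independent strands would give 20.5 in opposite directions (two-sided Fisher exact p = 0.0036, with hairpins of families not independent). Opposite pairs included miR-744, miR-23a and miR-196a, each with the 5p strand higher, and miR-1307, miR-28 and miR-330, each with the 3p strand higher. Strands under 100 RPM in cells carry the doubt about low values given above.

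The log2 change rose with the GC content of the hairpin, a relation tested after it was seen. Across 224 miRNAs with at least 100 RPM in either group Spearman's rho was 0.329 and Pearson's r 0.279 (permutation p = 1e-05 for rho, the smallest that 100000 permutations can give). miRNAs are not independent replicates. The median hairpin GC content was 53.0% for 79 miRNAs called higher and 46.5% for 91 called lower. The blood, liver and C14MC miRNAs alone are argued against as the reason, since without them rho was 0.408 across 205 miRNAs (permutation p = 1e-05). The GC content was that of the whole hairpin, averaged over the loci of a miRNA, and that of the mature strand was not measured. A GC-dependent loss in libraries made from little RNA may contribute, as might loading that depends on sequence, and neither was tested.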
